A study of Mus musculus with 16 samples.

How the data were processed

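RNA-seq was analysed from 16 mouse organoid libraries in 6 groups, taken from the sample titles: Ctr 3, LMP1 2, Lung-Ctr 2, Lung-LMP1 3, Normal_nasopha 3 and Normal_lung 3. Per the submitters' processing notes, the authors aligned reads with STAR to mm10 and used DESeq2 and DESeq. The counting tool, the gene annotation and all versions are not given in the sources used here. The authors deposited raw read counts per gene, per the file headers, and these counts are the only values tested here. Per the file headers, the authors also deposited log2 fold changes and adjusted p-values for 6 comparisons, whose calls at an adjusted p under 0.05 are quoted as those of the authors' deposited table. A further set of deposited columns, a scaled score headed as TPM, sums to between 150731 and 208938 per library and changes from table to table (Ctr replicate 1 by a factor of 1.2683), so this score was not used here. The 5 tables with gene symbols hold 24421 genes each and the table of normal tissues 51912 Ensembl entries. Of 27 symbols that had been turned into dates, 26 were restored from the reference annotation. There were 24781 Ensembl entries without a symbol, and of entries sharing a symbol 78 with the smaller total were kept apart under their identifier. The 13 columns that repeat a library in another table were identical, and 22549 symbols are shared by both kinds of table.

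The columns beside Ctr in the comparison with normal nasopharynx are headed as normal lung. They are called the normal comparator, and their tissue is not settled by the labels, while their counts argue against lung. Because the tables of tumours and of the 2 normal tissues use different gene identifiers, no fit joined all 16 libraries. Total counts per library run from 12535166 to 21737184, and a floor of 3 counts in 1 library is 0.138 to 0.2393 CPM. Floors and counting intervals cover counting error only. The labels do not say whether replicates of a group are separate animals or cultures, so p-values measure only the spread between these samples. Paralogs and overlapping genes cannot be told apart where the counting could split their reads.

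Counts were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr by group, TMM normalisation, robust dispersions, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment over the genes tested, at an adjusted p under 0.05. CPM (counts scaled to a common library total) in the comparisons are scaled by the TMM factors of the fit, and CPM of Trp53, Cdkn2a and Myc per library are by total count. The 10 tumour libraries were fitted together with 1 mean per group for LMP1 against Ctr, Lung-LMP1 against Lung-Ctr, Lung-Ctr against Ctr, Lung-LMP1 against LMP1 and their interaction, with 6 residual degrees of freedom. TMPL against TMP and Lung prefix against none used the same libraries with the other factor as a term. Ctr against the comparator and Normal_nasopha against Normal_lung each used their own 6 libraries. The 28 gene lists, of pathways, cell types and regional factors, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over the lists of a comparison. The median given for a list is that of the log2 fold changes of all its tested members. No list call of the 96 passed with an estimated correlation.

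The tests, the groups, the gene lists, the alternatives and the rule for named genes were set before the data were examined, except where stated. The rule names Trp53, Cdkn2a and Myc everywhere. It also names, in each comparison, the 6 called genes of largest log2 fold change in each direction (4 for the interaction), with a mean log2 CPM of at least 3, group ranges that do not overlap (not asked of the interaction) and no predicted symbol. For each list called it names the 3 members of smallest adjusted p in the list's direction, and for a list named without a call 2 members. Members of a list named beyond these, the genes high in Ctr replicate 2 and several genes of the plots were chosen after their values were seen. Some genes that the rule names are not reported here, and the counts of genes named by rule include them. Positions and identifiers are from GENCODE vM21 on GRCm38 (mm10), the build of the authors' alignment.

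Alternatives were DESeq2 1.42.0 on the same design, RLE size factors, no filter on low counts, each library left out in turn, the replicate number as a block, only the groups compared, no term for the other factor, and for lists camera with an estimated correlation and fry. A correction of each library for its smooth trend with transcript length and GC content (mgcv 1.9.3), and a fit of the 13 libraries of the symbol tables for Ctr against the comparator, were chosen after seeing the data. Length and GC content were those of the longest annotated transcript of each gene, so a trend with the transcripts actually expressed could remain. Principal components used the 1000 most variable genes as log2 CPM with a prior count of 2. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

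Each fit was tested on simulated data in which 200 genes were changed, 100 by 2-fold and 100 by 4-fold, and no changed gene was called in the wrong direction. The shares recovered at 2-fold and 4-fold were 4% and 53% for LMP1 against Ctr (13201 genes), 6% and 56% for Lung-LMP1 against Lung-Ctr (13211), 6% and 45% for Lung-Ctr against Ctr (13204), 11% and 60% for Lung-LMP1 against LMP1 (13213) and 0% and 19% for the interaction (13218). They were 28% and 70% for TMPL against TMP (12222), 37% and 70% for the Lung prefix (12240), 0% and 21% for Ctr against the comparator (12841) and 0% and 49% for Normal_nasopha against Normal_lung (15588). False calls made up 2% to 9.52% of calls.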

Results

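Polyadenylated RNA was sequenced from 16 libraries of mouse (C57BL/6) organoids, which are 3-dimensional cell cultures, in 6 groups named by the sample titles. Ctr (n = 3) and Lung-Ctr (n = 2) are tumour organoids of genotype TMP (Trp53-/-, Myc, sgCdkn2a), and LMP1 (n = 2) and Lung-LMP1 (n = 3) are tumour organoids of genotype TMPL, which adds LMP1, a signalling membrane protein of Epstein-Barr virus. Normal_nasopha (n = 3) and Normal_lung (n = 3) are organoids of normal nasopharynx and normal lung. The design text names primary and metastasized tumour organoids of both genotypes, whereas the sample descriptions call every TMP library primary and every TMPL library a metastasis. The groups are therefore given by their titles, and the Lung prefix is not equated with a site of growth. Total counts were 13617193, 13884804 and 14374166 in Ctr replicates 1 to 3, 18067227 and 14779383 in LMP1, 14360362 and 15053411 in Lung-Ctr, and 14767904, 16338921 and 12535166 in Lung-LMP1. They were 20672975, 21737184 and 20613034 in Normal_nasopha and 20138142, 21060707 and 20588330 in Normal_lung. A further 3 columns stand beside Ctr in the deposited comparison of Ctr with normal nasopharynx, with 16573082, 17631461 and 16627986 counts. Their column headings name normal lung, so they are called the normal comparator.

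Trp53, Cdkn2a and Myc are the mouse genes named in the genotype. Trp53 encodes the p53 tumour suppressor and lies on chromosome 11 from 69580359 to 69591873 (GRCm38, mm10). It was counted at 58.1, 77.9 and 65.7 CPM (its count as a share of the library's total, in the usual scaling) in Ctr replicates 1 to 3, 105 and 109 in LMP1, 58.3 and 86.0 in Lung-Ctr, and 81.8, 100.4 and 106.5 in Lung-LMP1. The normal comparator had 156, 100.3 and 63.3 CPM of Trp53, Normal_nasopha 136, 89.3 and 55.2, and Normal_lung 19.7, 33.9 and 27.4. Cdkn2a encodes the cell cycle inhibitors p16 and p19 and lies on chromosome 4 from 89274471 to 89294653. It was counted at 311, 229 and 219 CPM in Ctr, 381 and 331 in LMP1, 122 and 360 in Lung-Ctr, and 165, 292 and 187 in Lung-LMP1. The normal comparator had 4.83, 5.44 and 7.82 CPM of Cdkn2a, Normal_nasopha 3.97, 4.92 and 6.65, and Normal_lung 8.54, 7.60 and 7.29. Myc encodes a growth-promoting transcription factor and lies on chromosome 15 from 61985391 to 61990374. It was counted at 819, 667 and 627 CPM in Ctr, 2005 and 1841 in LMP1, 457 and 568 in Lung-Ctr, and 1211, 583 and 1068 in Lung-LMP1. The normal comparator had 100.04, 75.9 and 62.2 CPM of Myc, Normal_nasopha 93.6, 71.1 and 57.6, and Normal_lung 6.65, 15.2 and 7.58. The labels do not say which part of Trp53 or Cdkn2a was altered, so their counts do not check the genotype labels. The tables have no entry for viral LMP1, so the TMPL label could not be checked either.

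LMP1 and Ctr compare the 2 genotypes among libraries without the Lung prefix. Genes of epithelial identity and of the basal layer fell in LMP1. Grhl2, a transcription factor that maintains epithelial identity (chromosome 15, 37233036 to 37363569), fell 10.6-fold from 94.3 ± 29.6 CPM in Ctr (SD, n = 3) to 8.93 ± 2.93 in LMP1 (n = 2), with an adjusted p of 0.00286 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Lamb3, a laminin chain of the basement membrane (chromosome 1, 193207699 to 193343878), fell 25.3-fold from 120 ± 52.7 to 4.76 ± 1.73 CPM (edgeR adjusted p = 0.00245). Lgals1, a secreted galectin (chromosome 15, 78926725 to 78930465), rose 13.5-fold from 24.9 ± 12.9 to 335 ± 25.5 CPM (edgeR adjusted p = 0.00184). Myc rose 2.69-fold from 685 ± 94.2 to 1842 ± 99.5 CPM (log2 fold change 1.43 ± 0.28 SE, edgeR adjusted p = 0.0138). Trp53 was at 102 ± 3.28 against 65.4 ± 9.34 CPM (edgeR adjusted p = 0.0591) and Cdkn2a at 341 ± 31.7 against 246 ± 47.6 (edgeR adjusted p = 0.454), and neither passed.

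Of 13460 genes tested between LMP1 and Ctr, 991 rose and 1219 fell, 2210 in all. Among the largest rises were Col5a1, a fibrillar collagen chain, from 2.58 ± 3.9 to 124 ± 14 CPM (edgeR adjusted p = 0.0277), and Aebp1, a matrix-associated protein, from 6.04 ± 6.11 to 104 ± 12.6 (edgeR adjusted p = 0.00958). The glycerol phosphate dehydrogenase Gpd1 rose from 2.56 ± 2.68 to 59.8 ± 8.14 CPM (edgeR adjusted p = 0.0163), and fibronectin, Fn1, rose 16.4-fold from 35.2 ± 44.1 to 577 ± 18.5 (edgeR adjusted p = 0.0471). Stac2 rose from 2.72 ± 0.475 to 33.9 ± 13.3 CPM (edgeR adjusted p = 0.0135). Abca12, a lipid transporter of the skin barrier, fell from 57.9 ± 23.8 CPM to 0.059, which is 2 counts over both LMP1 libraries and a ratio of 994 with a 95% counting interval from 275 to 8220 (edgeR adjusted p = 0.00411). Krt15, a basal keratin, fell from 92.5 ± 128 to 0.224 ± 0.132 CPM (edgeR adjusted p = 0.0311), Phf11d from 59.3 ± 46.7 to 0.189 (edgeR adjusted p = 0.0262), and Usp18, an interferon-induced protease, from 46.1 ± 34.5 to 0.189 ± 0.193 (edgeR adjusted p = 0.028). Vimentin, Vim, did not pass (edgeR adjusted p = 0.29), with 1134 ± 218 CPM in LMP1, 359 CPM in Ctr replicate 2 and under 2 CPM in Ctr replicates 1 and 3. The same Ctr library also had 85.2 CPM of Fn1, 44.5 of Zeb1, 91.6 of Col3a1, 64.2 of Saa3 and 29.9 of Mgp, and on the principal component that sets the LMP1 libraries apart it lay at 23.19, against 87.16 and 97.8 in LMP1 and -37.92 to -10.04 in the other 7 tumour libraries. Without LMP1 replicate 1 the count of genes was 25 and 1 of the 31 genes named by rule kept its call, without LMP1 replicate 2 these were 126 and 8, and without Ctr replicate 3 they were 1454 and 25. Without Ctr replicate 1 or 2, 24 and 26 of those 31 genes kept their call.

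By gene list, 14 of 18 basal epithelial genes fell in LMP1, none rose and 4 were not called, and 17 fell when adjusted over the list alone. The basal list had a median log2 fold change of -4.89 (camera adjusted p = 2.34e-14, and adjusted p = 0.3 with an estimated correlation). It included the laminin receptor subunit Itga6, from 497 ± 95 to 129 ± 26 CPM. Of 22 epithelial genes 12 fell, none rose and 10 were not called (18 fell adjusted over the list alone), with a median of -1.80 (camera adjusted p = 6.35e-12, and adjusted p = 0.3 with an estimated correlation). The tight junction gene Cldn4 went from 302 ± 109 to 25 ± 9.79 CPM and the splicing regulator Esrp1 from 392 ± 117 to 72.5 ± 27.7. Of 18 squamous differentiation genes 9 fell and 9 were not called (11 fell adjusted over the list alone), with a median of -4.02, or -3.25 with members at 0 counts placed at their bound (camera adjusted p = 2.2e-06, and adjusted p = 0.3 with an estimated correlation). They included Krt6a, from 557 ± 409 to 9.97 ± 8.28 CPM, and the envelope protein Evpl, from 40.7 ± 10 to 7.34 ± 1.87. In the list of EMT (epithelial-mesenchymal transition) and mesenchymal genes 5 of 21 rose, 1 fell and 15 were not called (8 rose and 1 fell adjusted over the list alone), with a median of 1.51 (camera adjusted p = 0.00165, and adjusted p = 0.418 with an estimated correlation). The risers included Fn1, Snai1, Mmp2 and S100a4, whereas Snai2, also a basal-layer gene, fell.

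Interferon response genes were lower in LMP1, with 3 of 24 called, all falling, and 11 falling when adjusted over the list alone (median -4.33, camera adjusted p = 0.000165, and adjusted p = 0.755 with an estimated correlation). The RNA sensor Ddx58 fell from 113 ± 57.6 to 13.7 ± 1.04 CPM (edgeR adjusted p = 0.0387) and Ifit1 from 36.5 ± 37.5 to 0.185 ± 0.261 (edgeR adjusted p = 0.0319). In the list of MHC class I presentation genes 1 of 15 fell, the immunoproteasome subunit Psmb9, from 5.9 ± 2.55 to 0.582 ± 0.375 CPM, also the count adjusted over the list alone (median -1.31, camera adjusted p = 0.0446, and adjusted p = 0.755 with an estimated correlation). Of 22 Myc target and ribosome biogenesis genes 3 rose, Fbl, Rrp9 and Cdk4, and 19 were not called (2 rose adjusted over the list alone). Their median was 0.53 (camera adjusted p = 0.00437, and adjusted p = 0.755 with an estimated correlation). The nucleolar methyltransferase Fbl rose 2.08-fold from 104 ± 20.2 to 216 ± 4.08 CPM. Of 11 fibroblast genes 1 rose, Col5a1, also when adjusted over the list alone (median 1.02, camera adjusted p = 0.044, and adjusted p = 0.755 with an estimated correlation). NF-kB targets, a pathway that LMP1 is known to activate, did not pass as a list (camera adjusted p = 0.867), with 2 of 26 rising and 3 falling. Among them the inhibitor homologue Bcl3 rose (log2 fold change 1.41 ± 0.271 SE, edgeR adjusted p = 0.0133) and the chemokine Cxcl10 fell from 41.9 ± 18.4 to 1.38 ± 0.163 CPM (edgeR adjusted p = 0.0122). Fold changes followed the GC content of genes (rho = 0.362 across genes, which are not independent replicates), and a correction for transcript length and GC content, chosen after seeing the data, left 937 genes called. Of the 31 named genes 22 kept their call under it, and Col5a1, Fn1, Nipal4, Fbl, Rrp9, Cdk4, Ifit1, Ddx58 and Mmp2 did not.

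Lung-LMP1 and Lung-Ctr compare the same genotypes among libraries with the Lung prefix. Epithelial genes did not pass as a list here, while ribosome biogenesis and cholesterol genes lay higher and interferon genes lower in Lung-LMP1, without any single gene passing. Myc was at 1004 ± 355 CPM in Lung-LMP1 (n = 3) against 519 ± 79.2 in Lung-Ctr (n = 2; log2 fold change 0.95 ± 0.292 SE, edgeR adjusted p = 0.172). Trp53 was at 101 ± 11.7 against 73 ± 19.7 CPM (edgeR adjusted p = 0.293) and Cdkn2a at 225 ± 70.2 against 244 ± 171 (edgeR adjusted p = 0.914). Of 13460 genes edgeR's quasi-likelihood test called 0, with 2295 at an unadjusted p under 0.05 and a smallest adjusted p of 0.109, while DESeq2 called 881. There were 436 calls in the authors' deposited table, 287 higher and 149 lower. The stress transcription factor Atf4 was at 506 ± 56.9 against 197 ± 12 CPM (edgeR adjusted p = 0.109). Without Lung-Ctr replicate 1 the count was 7, and without Lung-Ctr replicate 2 it was 33.

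All 22 Myc target and ribosome biogenesis genes had a higher mean in Lung-LMP1 than in Lung-Ctr (median log2 fold change 0.83, camera adjusted p = 1.85e-07, and adjusted p = 0.74 with an estimated correlation), none called singly and 1 higher when adjusted over the list alone. Of 22 cholesterol synthesis genes 21 lay higher, none called singly and 7 when adjusted over the list alone (median 0.44, camera adjusted p = 1.85e-07, and adjusted p = 0.715 with an estimated correlation). All 24 interferon response genes lay lower (median -1.75, camera adjusted p = 2.95e-07, and adjusted p = 0.74 with an estimated correlation), as did all 15 MHC class I genes (median -0.70, camera adjusted p = 0.000355, and adjusted p = 0.74 with an estimated correlation). Neither list had a member called, either over all genes or adjusted over the list alone. Proliferation genes lay higher (median 0.60, camera adjusted p = 0.000195, and adjusted p = 0.715 with an estimated correlation), and so did squamous genes, 1 of them adjusted over the list alone (median 0.89, camera adjusted p = 0.00266, and adjusted p = 0.715 with an estimated correlation). Higher lists with 0 members called were also airway secretory genes (median 3.18, camera adjusted p = 0.00701, and adjusted p = 0.74 with an estimated correlation) and immediate early genes (median 0.45, camera adjusted p = 0.0407, and adjusted p = 0.754 with an estimated correlation). Basal genes (camera adjusted p = 0.157), epithelial genes (camera adjusted p = 0.398) and mesenchymal genes (camera adjusted p = 0.376) did not pass as lists. For mesenchymal genes the median was 0.30 while the mean was -0.12 with members at 0 counts placed at their bound. The log2 fold changes of LMP1 against Ctr and of Lung-LMP1 against Lung-Ctr, which share no library, had r = 0.0812 and rho = 0.266 across 13460 genes, which are not independent replicates. Of the 2210 genes called in LMP1 against Ctr, 77.7% had the same direction in both, where unrelated changes give about 50%. After the length and GC correction this was 66.9% of 937 genes, with rho = 0.23 across genes, which are not independent replicates.

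Lung-LMP1 and LMP1 compare libraries with and without the Lung prefix within TMPL. Epithelial, basal and squamous genes were higher and mesenchymal genes lower in Lung-LMP1. The same 2 LMP1 libraries stand in the comparison with Ctr, so opposite directions in the 2 comparisons are not independent. Grhl2 rose 12.9-fold from 8.93 ± 2.93 CPM in LMP1 (SD, n = 2) to 115 ± 10.2 in Lung-LMP1 (n = 3; edgeR adjusted p = 0.00208), and Lamb3 rose 40.3-fold from 4.76 ± 1.73 to 191 ± 39.4 (edgeR adjusted p = 0.00175). Vim (chromosome 2, 13573927 to 13582826), an intermediate filament of mesenchymal cells, fell from 1134 ± 218 to 0.363 ± 0.629 CPM, which is 17 counts (log2 fold change -11.45 ± 2.95 SE, edgeR adjusted p = 0.0429). Fn1 fell 47.7-fold from 577 ± 18.5 to 12.1 ± 4.83 CPM (edgeR adjusted p = 0.0272). Myc was at 1004 ± 355 against 1842 ± 99.5 CPM (log2 fold change -0.88 ± 0.28 SE, edgeR adjusted p = 0.0827) and did not pass, nor did Trp53 (edgeR adjusted p = 0.967) or Cdkn2a (edgeR adjusted p = 0.391).

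Of 13460 genes 830 were higher and 531 lower in Lung-LMP1 than in LMP1, 1361 in all. The mucosal keratin Krt13 (chromosome 11, 100117327 to 100121566) rose to 156 ± 144 CPM from 3 counts over the LMP1 libraries, a ratio of 1740 with a counting interval from 596 to 8450 (edgeR adjusted p = 0.0193). Abca12 rose to 73.8 ± 20.3 CPM from 2 counts, a ratio of 1240 with an interval from 342 to 10200 (edgeR adjusted p = 0.00365). Krt20, Oit1 and Dmrt3 rose to 40.9 ± 48.7, 15 ± 14.7 and 14.7 ± 14 CPM from 1 count each (edgeR adjusted p = 0.0364, 0.0497 and 0.026), and Oit1 was not called after the length and GC correction. The acute-phase gene Saa3 fell from 282 ± 46.9 to 0.232 ± 0.133 CPM (edgeR adjusted p = 0.0273) and the matrix protein Mgp from 194 ± 94.1 to 0.207 ± 0.119 (edgeR adjusted p = 0.0236). Col5a1 fell from 124 ± 14 CPM to 3 counts, a ratio of 1740 with an interval from 593 to 8420 (edgeR adjusted p = 0.0121). Peg10 fell from 34 ± 15 CPM to 1 count (edgeR adjusted p = 0.0421) and Prelp from 42.2 ± 18.9 to 2 counts (edgeR adjusted p = 0.0413). Without LMP1 replicate 1 the count of genes was 33 and 2 of the 37 genes named by rule kept their call, and without LMP1 replicate 2 these were 154 and 12. Without Lung-LMP1 replicates 1, 2 and 3 they were 949 and 26, 674 and 23, and 483 and 21.

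Of 18 basal genes 13 rose in Lung-LMP1 and 5 were not called (17 rose adjusted over the list alone), with a median of 5.40 (camera adjusted p = 2.63e-21, and adjusted p = 0.118 with an estimated correlation). Itga6 went from 129 ± 26 to 706 ± 95.6 CPM. Of 22 epithelial genes 13 rose and 9 were not called (18 rose adjusted over the list alone). Their median was 2.29 (camera adjusted p = 1.86e-18, and adjusted p = 0.118 with an estimated correlation). Esrp1 went from 72.5 ± 27.7 to 416 ± 38.5 CPM and the tight junction gene Cldn7 from 22.4 ± 7.31 to 262 ± 77.6. Of 18 squamous genes 10 rose and 8 were not called (11 rose adjusted over the list alone). Their median was 5.67, or 4.17 with members at 0 counts at their bound (camera adjusted p = 7.71e-13, and adjusted p = 0.118 with an estimated correlation). Krt4 went from 3.9 ± 0.742 to 416 ± 83.7 CPM. Cholesterol synthesis genes had 9 of 22 rising and 13 not called (14 rose adjusted over the list alone). Their median was 0.68 (camera adjusted p = 4.73e-06, and adjusted p = 0.306 with an estimated correlation). The synthase Hmgcs1 rose 2.09-fold from 289 ± 2.83 to 605 ± 54.5 CPM and the sterol oxidase Msmo1 from 193 ± 23.5 to 460 ± 40. In the mesenchymal list 9 of 21 genes fell and 12 were not called (15 fell and 3 rose adjusted over the list alone). Their median was -4.07 (camera adjusted p = 0.000446, and adjusted p = 0.306 with an estimated correlation). Mmp2 went from 17.9 ± 8.61 to 0.146 ± 0.0183 CPM and Snai1 from 23 ± 0.923 to 0.417 ± 0.0885.

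Ligands of the epidermal growth factor receptor were higher in Lung-LMP1 than in LMP1, Tgfa at 118 ± 21.7 against 19.4 ± 8.27 CPM (edgeR adjusted p = 0.00834) and Ereg at 218 ± 164 against 21.6 ± 6.28 (edgeR adjusted p = 0.0216). Of 20 genes in their list 5 rose and 15 were not called, with the same count adjusted over the list alone (median 0.72, camera adjusted p = 0.00325, and adjusted p = 0.513 with an estimated correlation). In the list of head and upper airway regional factors 4 of 13 rose, also when adjusted over the list alone, namely Pax9, Pitx1, Foxe1 and Tbx1 (median 0.07, mean 1.33, camera adjusted p = 0.0132, and adjusted p = 0.29 with an estimated correlation). Pax9, a pharyngeal transcription factor, rose 27.5-fold from 3.23 ± 0.142 to 89 ± 23.7 CPM (edgeR adjusted p = 0.00211) and Pitx1 rose from 3.49 ± 1.42 to 170 ± 91 (edgeR adjusted p = 0.00765). Airway secretory genes rose in 2 of 11 members, Muc4 and Lypd2 (4 rose adjusted over the list alone). Their median was 5.79 (camera adjusted p = 0.0132, and adjusted p = 0.715 with an estimated correlation). Fibroblast genes fell in 2 of 11, Col5a1 and Pdgfrb (8 fell adjusted over the list alone). Their median was -6.82, or -6.53 with members at 0 counts at their bound (camera adjusted p = 0.000186, and adjusted p = 0.482 with an estimated correlation). Endothelial genes fell in 1 of 5, Plvap, from 21.4 ± 5.53 to 0.5 ± 0.252 CPM, while 4 fell and 1 rose adjusted over the list alone (median -2.06, camera adjusted p = 0.0441, and adjusted p = 0.29 with an estimated correlation). Interferon genes (median 3.31, camera adjusted p = 0.00941, and adjusted p = 0.869 with an estimated correlation) and glycolysis genes (median 0.41, camera adjusted p = 0.0298, and adjusted p = 0.833 with an estimated correlation) passed as lists with 0 members called by edgeR.

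**Figure D1:**
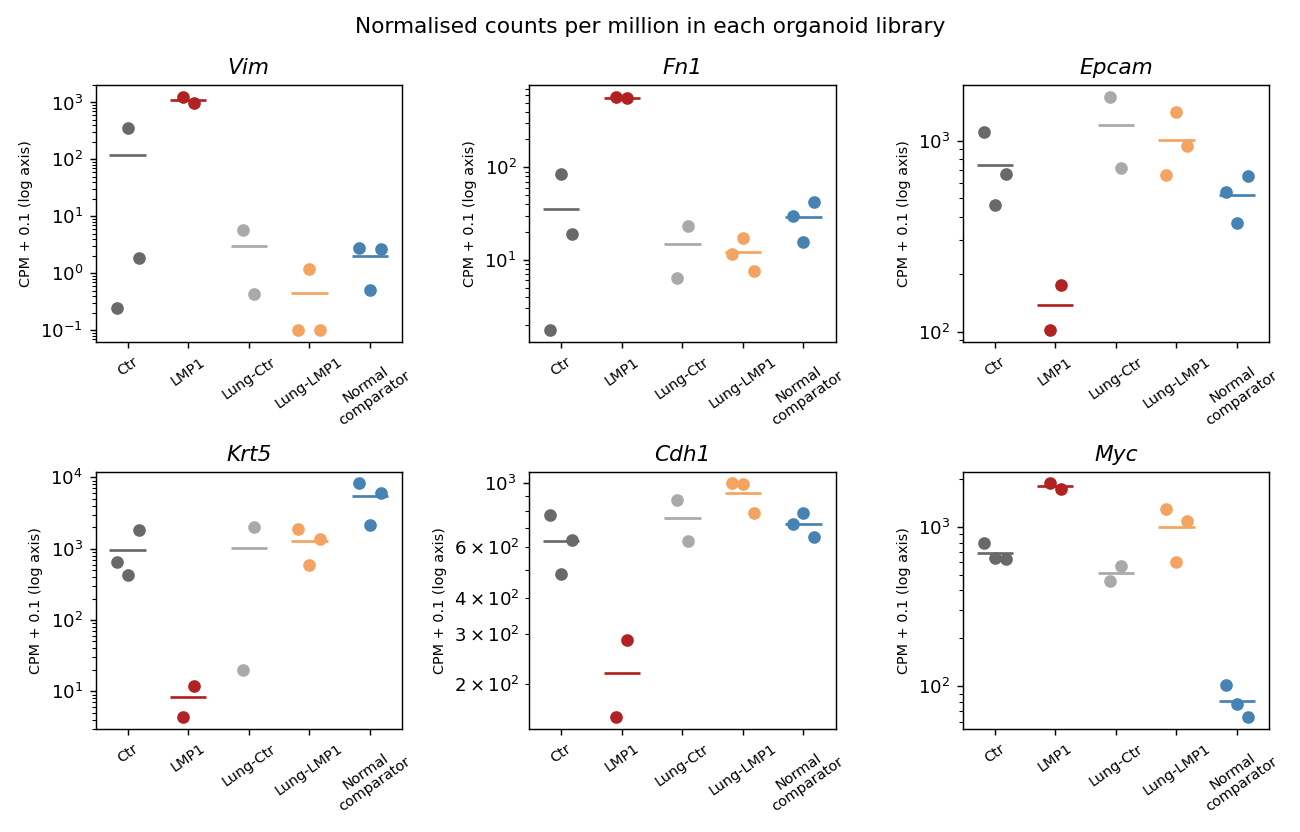
CPM plus 0.1 on a log axis of Vim, Fn1, Epcam, Krt5, Cdh1 and Myc in each library of Ctr, LMP1, Lung-Ctr, Lung-LMP1 and the normal comparator, with 1 point per library and a line at the group mean. Scaled over these 13 libraries, the LMP1 libraries lie at 962.2 and 1266 CPM of Vim, Ctr replicate 2 at 356 and the Lung-LMP1 libraries at 1.08 or less.

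The interaction of genotype and Lung prefix tests whether the TMPL minus TMP difference itself differs between libraries with and without the prefix. Grhl2 was at 94.3 ± 29.6 CPM in Ctr, 8.93 ± 2.93 in LMP1, 116 in Lung-Ctr and 115 ± 10.2 in Lung-LMP1, an interaction of 3.38 ± 0.456 SE on the log2 scale (edgeR adjusted p = 0.0239). Lamb3 was at 120, 4.76, 193 and 191 CPM in the same order (4.65 ± 0.585, edgeR adjusted p = 0.0218), and Esrp1 at 392, 72.5, 418 and 416 (2.43 ± 0.431, edgeR adjusted p = 0.0446). Of 13460 genes 109 had a positive and 11 a negative interaction, 120 in all. Krt23 was at 20.7 ± 21.6, 0.0977, 2.1 and 15.7 ± 10.6 CPM (edgeR adjusted p = 0.0469), Abca12 at 57.9, 0.059, 54.3 and 73.8 (edgeR adjusted p = 0.0239), the platelet chemokine Ppbp at 73.8, 0.612, 14.4 and 123 (edgeR adjusted p = 0.0402) and Vnn1 at 19.9, 0.15, 2.38 and 12.7 (edgeR adjusted p = 0.0407). These 4 had 3, 2, 19 and 5 counts over the LMP1 libraries. Negative interactions included the RNA-binding protein gene Pcbp4, at 21.4, 161, 12.7 and 7.47 CPM (-3.67 ± 0.6, edgeR adjusted p = 0.0395), Gpsm1, at 5.49, 11.2, 13.9 and 4.03 (-2.82 ± 0.452, edgeR adjusted p = 0.0395), Rgma, at 10.9, 44, 18.1 and 11.2 (-2.70 ± 0.495, edgeR adjusted p = 0.0481), and Amotl2, at 62.3, 141, 154 and 59.3 (-2.55 ± 0.415, edgeR adjusted p = 0.0395). After the length and GC correction 13 of the 17 genes named by rule kept their call, and Pcbp4, Gpsm1, Rgma and Hmgcs1 did not. Trp53 (edgeR adjusted p = 0.826), Cdkn2a (edgeR adjusted p = 0.695) and Myc (-0.47 ± 0.399, edgeR adjusted p = 0.627) showed no called interaction.

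In the interaction 2 of 18 basal genes were called, Lamb3 among them, both positive, and 14 when adjusted over the list alone (median 5.47, camera adjusted p = 4.74e-24, and adjusted p = 0.0801 with an estimated correlation). Of 18 squamous genes 1 was called, Cnfn, and 10 adjusted over the list alone (median 5.46, camera adjusted p = 2.79e-14, and adjusted p = 0.0801 with an estimated correlation). Of 22 epithelial genes 3 were called, Grhl2, Cldn7 and Esrp1, and 13 adjusted over the list alone (median 1.97, camera adjusted p = 4.88e-16, and adjusted p = 0.186 with an estimated correlation). Airway genes had 0 of 11 called by edgeR and 5 adjusted over the list alone (median 7.98, camera adjusted p = 5.93e-05, and adjusted p = 0.475 with an estimated correlation). Cholesterol genes had 1 of 22 called, Hmgcs1, and 6 adjusted over the list alone (median 0.45, camera adjusted p = 0.000736, and adjusted p = 0.527 with an estimated correlation). Head regional factors had 2 of 13 called, Pax9 and Pitx1, and 3 adjusted over the list alone (median 0.50, camera adjusted p = 0.0144, and adjusted p = 0.305 with an estimated correlation). Mesenchymal genes had a negative interaction as a list, with none called singly and 3 adjusted over the list alone (median -1.28, camera adjusted p = 0.0167, and adjusted p = 0.475 with an estimated correlation). EGFR ligand genes (median 0.70, camera adjusted p = 0.022, and adjusted p = 0.715 with an estimated correlation) and fibroblast genes (median -1.97, camera adjusted p = 0.0316, and adjusted p = 0.817 with an estimated correlation) had no member called over all genes, and 1 EGFR ligand gene when adjusted over the list alone. The 120 genes became 4 without LMP1 replicate 1, 5 without LMP1 replicate 2, 9, 23 and 9 without Lung-LMP1 replicates 1, 2 and 3, 43, 331 and 66 without Ctr replicates 1, 2 and 3, and 53 and 274 without Lung-Ctr replicates 1 and 2. Of the 17 named genes those fits kept 0, 0, 0, 1, 0, 4, 17, 9, 1 and 12 in the same order.

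**Figure D2:**
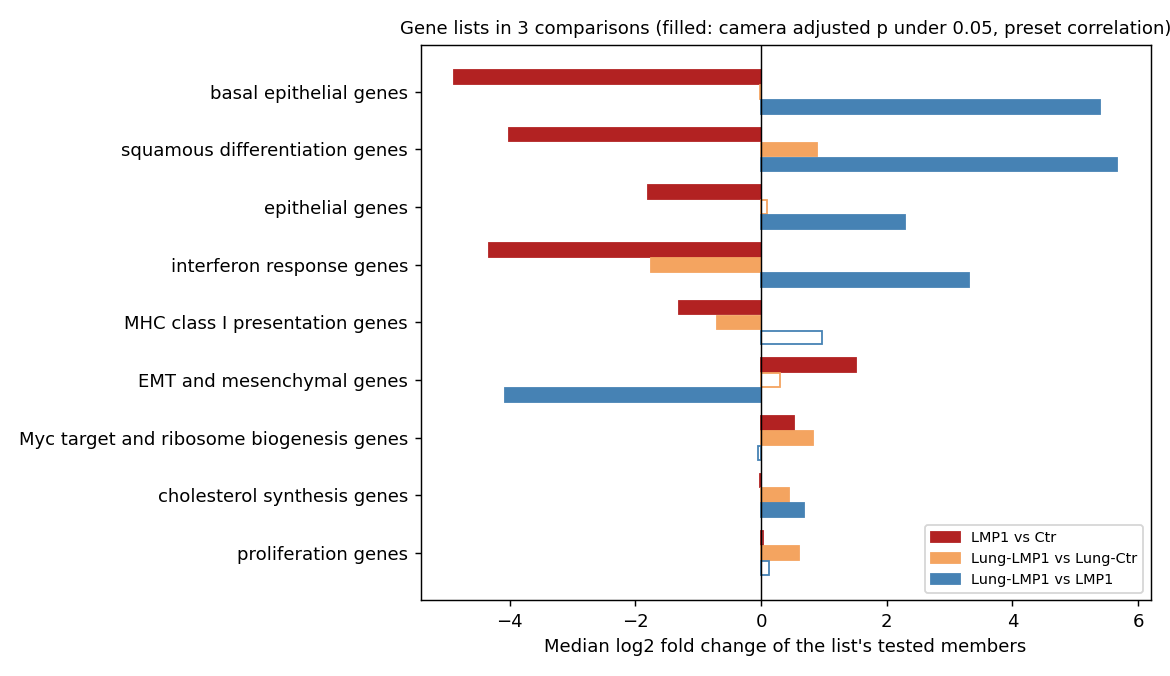
Median log2 fold change of 9 gene lists in LMP1 against Ctr, Lung-LMP1 against Lung-Ctr and Lung-LMP1 against LMP1, with 1 bar per list and comparison, filled where camera passed with the preset correlation. Basal genes lie at -4.89 in LMP1 against Ctr and at 5.40 in Lung-LMP1 against LMP1, which share the LMP1 libraries.

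Lung-Ctr and Ctr compare libraries with and without the Lung prefix within TMP, and here no single gene passed. Myc was at 519 ± 79.2 CPM in Lung-Ctr (SD, n = 2) against 685 ± 94.2 in Ctr (n = 3; log2 fold change -0.40 ± 0.287 SE, edgeR adjusted p = 0.917), Trp53 at 73 ± 19.7 against 65.4 ± 9.34 (edgeR adjusted p = 0.935), and Cdkn2a did not pass either (edgeR adjusted p = 0.997). The stem cell factor Sox2 was at 119 ± 74 against 51 ± 12.5 CPM and was not called. Of 13460 genes edgeR's quasi-likelihood test called 0, with 717 at an unadjusted p under 0.05 and a smallest adjusted p of 0.635, while DESeq2 called 40 and there were 28 calls in the authors' deposited table, with 17 higher and 11 lower. Without Lung-Ctr replicate 2 the count was 31. Glycolysis and hypoxia genes lay higher in Lung-Ctr as a list (median 0.40, camera adjusted p = 6.45e-06), as did interferon (0.79, camera adjusted p = 0.000362), MHC class I (0.35, camera adjusted p = 0.0196), Wnt target (0.36, camera adjusted p = 0.0378) and Notch pathway genes (0.51, camera adjusted p = 0.04). Lists that lay lower were Myc targets (median -0.37, camera adjusted p = 0.00233), NF-kB targets (-0.12, camera adjusted p = 0.00377), proliferation genes (-0.34, camera adjusted p = 0.00952), airway secretory genes (-3.06, camera adjusted p = 0.00644), mesenchymal genes (-0.93, camera adjusted p = 0.04) and fibroblast genes (-4.56, or -2.76 with members at 0 counts at their bound, camera adjusted p = 0.00543). Each of these lists had an adjusted p of 0.722 with an estimated correlation and 0 members called by edgeR, over all genes or adjusted over the list alone. Basal (median 0.49, camera adjusted p = 0.253), epithelial (0.29, camera adjusted p = 0.0714) and squamous genes (0.31, camera adjusted p = 0.392) did not pass as lists. Ctr replicate 2 had 91.6 CPM of the fibroblast list's Col3a1 and 44.5 CPM of the mesenchymal list's Zeb1.

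TMPL and TMP compare all 5 libraries of each genotype with the Lung prefix as a term in the model. The sample descriptions call TMP libraries primary and TMPL libraries metastases, which the design text does not. If the descriptions hold, genotype and metastasis cannot be told apart here. The same applies to LMP1 against Ctr and to Lung-LMP1 against Lung-Ctr. Myc rose 2.28-fold from 621 ± 121 CPM in TMP (SD, n = 5) to 1340 ± 530 in TMPL (n = 5; log2 fold change 1.19 ± 0.21 SE, edgeR adjusted p = 0.00938). Among the largest rises were Atp5k, a subunit of the mitochondrial ATP synthase (chromosome 5, 108433244 to 108434448), 12.4-fold from 3.51 ± 2.94 to 34.6 ± 7.43 CPM (edgeR adjusted p = 0.00447), and the actin-binding thymosin Tmsb10 from 18.2 ± 11.9 to 103 ± 17.6 (edgeR adjusted p = 0.00564). The RNA polymerase subunit Polr2j rose from 9.41 ± 2.85 to 37 ± 7.31 CPM (edgeR adjusted p = 0.00385), the phosphatase inhibitor Ppp1r14b from 33.5 ± 7.48 to 144 ± 53.1 (edgeR adjusted p = 0.0035), the mitochondrial ribosomal protein Mrps21 from 9.33 ± 2.53 to 34.2 ± 6.31 (edgeR adjusted p = 0.00313) and Hypk from 8.13 ± 1.32 to 31.6 ± 13.6 (edgeR adjusted p = 0.00479). Trp53 rose 1.47-fold from 68.6 ± 12.3 to 101 ± 8.32 CPM (edgeR adjusted p = 0.0309), and its adjusted p was 0.071 after the length and GC correction, while Cdkn2a did not pass (edgeR adjusted p = 0.721). The tight junction gene Cldn8 fell from 52.3 ± 38 to 6.56 ± 5 CPM (edgeR adjusted p = 0.0137), the urokinase Plau from 142 ± 33.8 to 51.1 ± 37.3 (edgeR adjusted p = 0.0263) and Tdrp from 16.1 ± 31 to 0.378 ± 0.167 (edgeR adjusted p = 0.028), with Lung-Ctr replicate 2 at 71.42 CPM of Tdrp. Smaller falls included Tbc1d16 (log2 fold change -1.57, edgeR adjusted p = 0.0117) and the deubiquitinase Yod1 (-1.50, edgeR adjusted p = 0.0151).

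Of 12359 genes 955 were higher and 739 lower in TMPL than in TMP, 1694 in all, of which 422 differed by more than 2-fold. The balance of directions depended on the method, with 1385 higher and 1730 lower by DESeq2 and 628 higher and 168 lower after the length and GC correction. In the Myc target and ribosome biogenesis list 6 of 22 rose and 16 were not called (10 rose adjusted over the list alone). Their median was 0.65 (camera adjusted p = 9.32e-07, and adjusted p = 0.81 with an estimated correlation). Fbl went from 92.4 ± 22.5 to 204 ± 45 CPM (edgeR adjusted p = 0.00695). Cholesterol synthesis genes rose in 5 of 22 members, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.0266, and adjusted p = 0.81 with an estimated correlation). In LMP1 against Ctr alone the cholesterol list did not pass, with 3 members rising and 4 falling (median -0.0123, camera adjusted p = 0.988). The decarboxylase Mvd went from 26.9 ± 4.95 to 56.9 ± 10.9 CPM (edgeR adjusted p = 0.00479). Interferon response genes had 1 of 23 falling, the antiviral Rsad2, from 88.2 ± 60.8 to 10.2 ± 15.1 CPM (edgeR adjusted p = 0.0425), and 0 by edgeR when adjusted over the list alone (median -2.97, camera adjusted p = 4.89e-07, and adjusted p = 0.81 with an estimated correlation). The sides overlap, with Ctr replicate 3 at 4.655 CPM of Rsad2 and Lung-LMP1 replicate 2 at 37.14, scaled over 13 libraries. MHC class I genes fell in 4 of 15 members, Tap1, Psmb8, Psmb9 and Erap1, and in 5 adjusted over the list alone (median -1.23, camera adjusted p = 0.000753, and adjusted p = 0.81 with an estimated correlation). Psmb8 went from 12 ± 7.6 to 1.99 ± 1.8 CPM (edgeR adjusted p = 0.0235). Of 18 immediate early genes 1 rose, Jund, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.0293, and adjusted p = 0.81 with an estimated correlation). Epithelial (median -0.77, camera adjusted p = 0.00607) and basal genes (median -2.63, camera adjusted p = 0.0062) were lower as lists with 0 members called by edgeR, and each had an adjusted p of 0.81 with an estimated correlation. Both lists were lower in LMP1 against Ctr (medians -1.80 and -4.89) and did not pass in Lung-LMP1 against Lung-Ctr (medians 0.0994 and -0.00969). Without LMP1 replicates 1 and 2 the count of genes was 489 and 362, without Lung-LMP1 replicate 1 it was 1097 and without Ctr replicate 2 it was 1017. Of the 25 genes named by rule these 4 fits kept 12, 10, 19 and 17, and leaving out Lung-LMP1 replicates 2 and 3, Ctr replicates 1 and 3 and Lung-Ctr replicates 1 and 2 kept 23, 20, 22, 24, 21 and 24. Genes called higher had a median GC content of 54.9% against 42.8% for those called lower, and 796 genes were called after the length and GC correction, with 18 of the 25 named genes among them. Trp53, Rrp9, Cdk4, Rsad2, Erap1, Jund and Yod1 were the named genes that were not.

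Libraries with and without the Lung prefix were also compared across both genotypes, with genotype as a term, 5 against 5. Myc was at 809 ± 369 CPM with the prefix against 1152 ± 640 without it (log2 fold change -0.64 ± 0.208 SE, edgeR adjusted p = 0.213), and neither Trp53 (edgeR adjusted p = 0.846) nor Cdkn2a (edgeR adjusted p = 0.603) passed. Of 12359 genes edgeR's quasi-likelihood test called 0, with 2044 at an unadjusted p under 0.05 and a smallest adjusted p of 0.1, while DESeq2 called 966, and the authors' deposited table has no such comparison. The count was 110 without Lung-Ctr replicate 1, 152 without Lung-Ctr replicate 2 and 3 without Ctr replicate 1. Basal genes lay higher with the prefix (median 2.88, camera adjusted p = 1.57e-09, and adjusted p = 0.346 with an estimated correlation), 4 of them adjusted over the list alone. Epithelial (median 1.23, camera adjusted p = 5.72e-10), squamous (2.11, camera adjusted p = 8.53e-07), glycolysis (0.43, camera adjusted p = 1.01e-05) and cholesterol genes (0.39, camera adjusted p = 1.3e-05) also lay higher, each with an adjusted p of 0.346 with an estimated correlation and at most 1 member adjusted over the list alone. Of these 5 lists only glycolysis genes also passed within TMP, whereas all 5 passed within TMPL. Notch genes were higher as a list with 3 higher and 1 lower adjusted over the list alone (median 0.51, camera adjusted p = 0.0118, and adjusted p = 0.346 with an estimated correlation). Interferon genes (median 1.90, camera adjusted p = 2.34e-05, and adjusted p = 0.539 with an estimated correlation), EGFR ligand genes (median 0.35, camera adjusted p = 0.00397, and adjusted p = 0.364 with an estimated correlation) and MHC class I genes (median 0.76, camera adjusted p = 0.0313, and adjusted p = 0.76 with an estimated correlation) were higher too. Myc targets were lower (median -0.22, camera adjusted p = 0.0125, and adjusted p = 0.804 with an estimated correlation).

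Ctr and the normal comparator set TMP tumour organoids against normal organoids. Cdkn2a rose 39.8-fold from 6.2 ± 1.66 CPM in the comparator (SD, n = 3) to 247 ± 45.1 in Ctr (n = 3; log2 fold change 5.31 ± 0.316 SE, edgeR adjusted p = 0.0028), and Myc rose 8.43-fold from 81.5 ± 19.3 to 687 ± 86.7 (3.08 ± 0.268 SE, edgeR adjusted p = 0.00741). Trp53 was at 65.6 ± 9.48 against 109 ± 47.6 CPM (-0.74 ± 0.342 SE, edgeR adjusted p = 0.153) and did not pass. Targets of p53 fell, the cell cycle inhibitor Cdkn1a 11.1-fold from 396 ± 173 to 35.8 ± 18.8 CPM (edgeR adjusted p = 0.0104), the apoptosis gene Bax 7.74-fold from 224 ± 29.5 to 28.9 ± 7.03 (edgeR adjusted p = 0.00741) and Phlda3 from 434 ± 123 to 51.6 ± 34.7 (edgeR adjusted p = 0.0121). In the p53 target list 11 of 22 genes fell, 1 rose, Rrm2b, and 10 were not called (12 fell and 1 rose adjusted over the list alone). Their median was -1.13 (camera adjusted p = 3.75e-05, and adjusted p = 0.22 with an estimated correlation). Across genes, which are not independent replicates, the comparator libraries had r of 0.9811 to 0.9816 with the Normal_nasopha library of the same number, 0.949 to 0.9574 with the other Normal_nasopha libraries and 0.8944 to 0.911 with Normal_lung. Sftpc was at 30.1 to 134 CPM by total count in the comparator, against 37317 to 45810 in Normal_lung. These values argue against lung as the tissue of the comparator. Its columns are best read as the Normal_nasopha libraries counted on another gene list, not as further samples.

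Of 13034 genes 1261 were higher and 1656 lower in Ctr than in the comparator, 2917 in all. Genes of the Y chromosome were counted in Ctr and at 0 in the comparator, Ddx3y at 103 ± 24.5 CPM, at least 552-fold higher against a floor of 3 counts in 1 library (edgeR adjusted p = 0.00517), Eif2s3y at 69.1 ± 16.2, at least 371-fold (edgeR adjusted p = 0.00642), and Uty at 48.4 ± 12.5, at least 260-fold (edgeR adjusted p = 0.00735). Sex-linked genes passed as a list with 4 of 5 rising and Xist falling, also when adjusted over the list alone (median 12.50, or 8.02 with members at 0 counts at their bound, camera adjusted p = 1.55e-07, and adjusted p = 0.22 with an estimated correlation). Xist was at 0.213 to 1.18 CPM in Ctr and 1070 to 1140 in the comparator. By these genes the Ctr cells are read as male and those of the comparator as female. Sex therefore runs along with tumour against normal here, and their effects cannot be told apart in the calls. The monocyte chemokine Ccl2 rose 174-fold from 1.03 ± 1.42 to 180 ± 56.5 CPM (edgeR adjusted p = 0.0106), and Sim2 was at 25.4 ± 38.8 in Ctr against 1 count, a ratio of 1250 with a counting interval from 224 to 49400 (edgeR adjusted p = 0.022). The secreted airway protein Bpifb4 was at 0 in Ctr against 1280 ± 1610 CPM, at least 6050-fold lower (edgeR adjusted p = 0.0136), Bpifb9a at 0 against 71.9 ± 67, at least 340-fold (edgeR adjusted p = 0.0154), and surfactant protein Sftpc at 0 against 66.6 ± 60.6, at least 315-fold (edgeR adjusted p = 0.0106). Sftpc lay at only 0.0644% to 0.297% of its lung level in Normal_nasopha, so its absence in Ctr does not show a loss by tumour cells. Without Ctr replicates 1, 2 and 3 the count of genes was 1366, 718 and 849, and without comparator replicate 3 it was 955. Of the 45 genes named by rule these 4 fits kept 34, 30, 34 and 32, and without comparator replicates 1 and 2, 41 and 42 kept their call. Fold changes ran against GC content (rho = -0.391 across genes, which are not independent replicates), and 1390 genes were called after the length and GC correction, with 38 of the 45 named genes among them. The named genes that were not are Ugt2a1, Npm1, Chac1, Creld2, Krt14, Lypd2 and Six2.

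Squamous genes fell in Ctr in 9 of 20 members with 11 not called (14 fell adjusted over the list alone). Their median was -3.35 (camera adjusted p = 1.03e-07, and adjusted p = 0.227 with an estimated correlation). Krt16 went from 794 ± 369 to 7.64 ± 7.26 CPM (edgeR adjusted p = 0.00978) and the envelope protein Cnfn from 46.9 ± 15.8 to 1.42 ± 0.516 (edgeR adjusted p = 0.00741). Alveolar genes fell in 10 of 18 with Rtkn2 rising (13 fell and 1 rose adjusted over the list alone). Their median was -4.30, or -4.15 with members at 0 counts at their bound (camera adjusted p = 0.000168, and adjusted p = 0.759 with an estimated correlation). The 5 alveolar genes most abundant in lung lay at 0.278% to 0.339% of their lung level in Normal_nasopha replicate 1, so this fall does not show a loss of alveolar expression by tumour cells. Basal genes fell in 5 of 18, also adjusted over the list alone (median -1.52, camera adjusted p = 0.00477, and adjusted p = 0.777 with an estimated correlation). Krt14 went from 3477 ± 2890 to 229 ± 246 CPM. Airway genes fell in 4 of 13, also adjusted over the list alone (median -3.58, camera adjusted p = 0.00562, and adjusted p = 0.764 with an estimated correlation). Bpifa1 went from 238 ± 315 to 0.139 ± 0.183 CPM. Unfolded protein response genes fell in 8 of 20 with Edem1 rising (10 fell and 1 rose adjusted over the list alone). Their median was -0.87 (camera adjusted p = 0.0266, and adjusted p = 0.764 with an estimated correlation). The chaperone Pdia4 went from 219 ± 66.6 to 90 ± 17.7 CPM. Matrix proteases and inhibitors fell in 6 of 21 with Plau rising (7 fell and 1 rose adjusted over the list alone). Their median was -0.997 (camera adjusted p = 0.0415, and adjusted p = 0.703 with an estimated correlation). Plaur went from 219 ± 88.8 to 24.6 ± 11.6 CPM. Head regional factors fell in 3 of 16, Six2, Otx2 and Dlx5, also adjusted over the list alone (median -1.47, camera adjusted p = 0.0191, and adjusted p = 0.759 with an estimated correlation).

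NF-kB targets rose in Ctr in 5 of 26 members, Rel, Birc3, Cxcl10, Ccl2 and Nfkbie, and in 4 adjusted over the list alone (median 1.31, camera adjusted p = 0.000374, and adjusted p = 0.764 with an estimated correlation). Cxcl10 went from 2.54 ± 2.92 to 41.9 ± 17.9 CPM (edgeR adjusted p = 0.0252). Interferon genes rose in 2 of 24, Usp18 and Ddx58, and in 1 adjusted over the list alone (median 1.90, camera adjusted p = 0.00397, and adjusted p = 0.782 with an estimated correlation). Ddx58 went from 21.9 ± 1.19 to 112 ± 56.5 CPM (edgeR adjusted p = 0.0154). Proliferation genes were higher as a list with 0 of 24 called by edgeR (median 1.54, camera adjusted p = 0.000173, and adjusted p = 0.777 with an estimated correlation), and Myc targets with 1 of 22 called, Npm1, and 0 by edgeR adjusted over the list alone (median 0.69, camera adjusted p = 0.0172, and adjusted p = 0.788 with an estimated correlation). In the list of lung regional factors 3 of 6 rose, also adjusted over the list alone (median 5.15, or 2.88 with members at 0 counts at their bound, camera adjusted p = 0.00108, and adjusted p = 0.227 with an estimated correlation). The 3 were the anterior homeobox genes Hoxa3 (chromosome 6, 52169062 to 52213336), Hoxa4 and Hoxa5, at 14.3 ± 8.03, 3.36 ± 1.28 and 5.73 ± 0.958 CPM against 0, at least 76.9-fold, 18.1-fold and 30.8-fold higher, whereas Nkx2-1, the lung identity factor, had 0 counts in every tumour library.

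Normal_nasopha and Normal_lung compare the 2 normal tissues. Nkx2-1, the transcription factor of lung identity (chromosome 12, 56531958 to 56536908), fell 787-fold from 969 ± 148 CPM in Normal_lung (SD, n = 3) to 1.23 ± 1.3 in Normal_nasopha (n = 3; edgeR adjusted p = 0.000556), and the lamellar body transporter Abca3 fell 38-fold from 1954 ± 128 to 51.4 ± 3.36 (edgeR adjusted p = 0.000128). By total count, Normal_nasopha replicates 1 to 3 had 2.90, 0.460 and 0.534 CPM of Nkx2-1 and 121.9, 28.7 and 26.4 of Sftpc. Lung material or reads may thus set the fold of Nkx2-1, and of other lung genes at a trace level in Normal_nasopha. This was not tested for these genes. Six2, a craniofacial transcription factor (chromosome 17, 85684277 to 85688274), was at 71 ± 12.8 CPM in Normal_nasopha against 1 count in Normal_lung, a ratio of 4150 with a counting interval from 745 to 164000 (edgeR adjusted p = 0.000128). The basal keratin Krt17 rose 253-fold from 8.36 ± 9.68 to 2110 ± 1080 CPM (edgeR adjusted p = 0.00276). Myc rose 6.86-fold from 10.3 ± 4.53 to 70.4 ± 16.9 (edgeR adjusted p = 0.00205) and Trp53 3.13-fold from 28.4 ± 6.58 to 88.8 ± 37.9 (edgeR adjusted p = 0.0137), while Cdkn2a, at 4.92 ± 1.28 against 8.25 ± 0.873, did not pass (edgeR adjusted p = 0.116). Of 15886 genes 2451 were higher and 2484 lower in Normal_nasopha, 4935 in all. Sp8 was at 26.8 ± 13.7 CPM against 1 count (ratio 1560, interval 280 to 61700, edgeR adjusted p = 0.000538), and Sult1c1 at 38.2 ± 35.1 against 1 count (ratio 2220, interval 398 to 87700, edgeR adjusted p = 0.00198). Retnla fell from 91 ± 30.6 to 0.0761 ± 0.0696 CPM (edgeR adjusted p = 0.000204), Sfta3-ps from 521 ± 92 to 0.576 ± 0.612 (edgeR adjusted p = 0.000396), and endothelin 3, Edn3, from 17.2 ± 8.41 to 0, at least 125-fold (edgeR adjusted p = 0.00131). Without Normal_lung replicates 1, 2 and 3 the count was 3050, 3185 and 2657, and 59, 59 and 58 of the 62 genes named by rule kept their call. Without Normal_nasopha replicates 1, 2 and 3 these were 61, 61 and 60.

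All 18 alveolar genes fell in Normal_nasopha, also adjusted over the list alone (median -8.77, camera adjusted p = 2.38e-31, and adjusted p = 0.188 with an estimated correlation). The aspartic protease Napsa went from 1055 ± 38.4 to 1.6 ± 1.25 CPM (edgeR adjusted p = 0.000284). All 13 lung regional factors tested fell too (median -5.67, or -5.38 with members at 0 counts at their bound, camera adjusted p = 6.28e-11, and adjusted p = 0.223 with an estimated correlation). Foxa2 went from 171 ± 12.5 to 0.303 ± 0.408 CPM (edgeR adjusted p = 0.000493). Of 16 head regional factors 15 rose, also adjusted over the list alone (median 6.24, or 5.55 at the bound, camera adjusted p = 7.83e-15, and adjusted p = 0.223 with an estimated correlation). The eye and nasal factor Pax6 rose 487-fold from 0.118 ± 0.0559 to 60.9 ± 26.8 CPM (edgeR adjusted p = 0.000208). Basal genes rose in 13 of 18 with 1 falling (15 rose and 1 fell adjusted over the list alone). Their median was 4.88 (camera adjusted p = 2.81e-06). The laminin chain Lama3 rose 27.3-fold from 8.61 ± 0.919 to 235 ± 92.7 CPM. Squamous genes rose in 9 of 21 (10 adjusted over the list alone). Their median was 3.45 (camera adjusted p = 0.00081). Sprr1a went from 6.77 ± 4.01 to 624 ± 242 CPM. Myc targets rose in 16 of 22 (19 adjusted over the list alone). Their median was 1.56 (camera adjusted p = 8.81e-05). Mybbp1a went from 71.8 ± 13 to 290 ± 124 CPM. Each of these 3 lists had an adjusted p of 0.615 with an estimated correlation.

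Signalling lists also passed between the normal tissues, each with an adjusted p of 0.615 with an estimated correlation. EGFR ligand and ERK feedback genes rose in 10 of 20 and fell in 3 (11 and 3 adjusted over the list alone). Their median was 0.87 (camera adjusted p = 0.0324). The phosphatase Dusp5 rose 27.2-fold from 2.25 ± 0.469 to 61.3 ± 21 CPM. Notch genes rose in 7 of 12 (7 rose and 2 fell adjusted over the list alone). Their median was 1.91 (camera adjusted p = 0.0205). The receptor Notch1 went from 18.1 ± 1.08 to 170 ± 67.7 CPM. Immediate early genes rose in 10 of 18 and Btg2 fell (11 and 1 adjusted over the list alone). Their median was 1.46 (camera adjusted p = 0.00278). Klf4 went from 8.15 ± 2.46 to 85.1 ± 25.7 CPM. Unfolded protein response genes rose in 7 of 20 with Sel1l falling (median 0.81, camera adjusted p = 0.0134), glycolysis genes in 9 of 24 with Vegfa falling (median 0.57, camera adjusted p = 0.0324), and mesenchymal genes fell in 9 of 18 with Snai2 and Tgfbi rising (median -2.43, camera adjusted p = 0.0315), with the same counts adjusted over the list alone. The glycolytic hexokinase Hk2 rose from 50.3 ± 8.73 to 194 ± 44.8 CPM and Fn1 fell 16.2-fold from 383 ± 143 to 23.6 ± 9.97. Fibroblast genes fell in 11 of 11, also adjusted over the list alone (median -5.32, camera adjusted p = 5.68e-07, and adjusted p = 0.519 with an estimated correlation). The collagen chain Col6a1 went from 101 ± 25.6 to 1.46 ± 1.04 CPM. Targets of p53 rose in 8 of 22 with Btg2 falling (10 rose and 2 fell adjusted over the list alone). Their median was 0.50 (camera adjusted p = 0.0121, and adjusted p = 0.519 with an estimated correlation). The apoptosis gene Pmaip1 rose 66.6-fold from 1.63 ± 0.879 to 108 ± 31.4 CPM (edgeR adjusted p = 0.000334). Ciliated cell genes fell in 6 of 12 with Rsph1 rising (7 and 1 adjusted over the list alone). Their median was -2.28 (camera adjusted p = 0.0109, and adjusted p = 0.391 with an estimated correlation). Interferon genes fell in 6 of 24, also adjusted over the list alone, with Ddx58 from 56.2 ± 13 to 19.1 ± 1.28 CPM (median -1.09, camera adjusted p = 0.0369, and adjusted p = 0.769 with an estimated correlation). Immune cell genes fell in 3 of 12, Csf1r, C1qb and C1qc, with Cd68 rising (6 and 1 adjusted over the list alone). Their median was -3.14 (camera adjusted p = 0.04, and adjusted p = 0.716 with an estimated correlation).

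**Figure D3:**
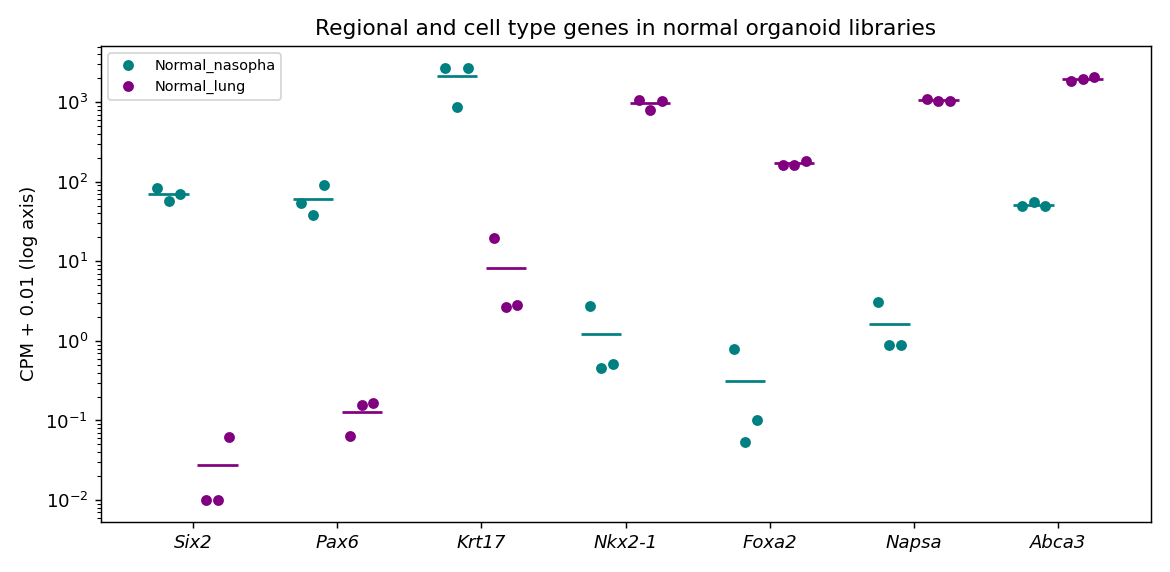
CPM plus 0.01 on a log axis of Six2, Pax6, Krt17, Nkx2-1, Foxa2, Napsa and Abca3 in each library of Normal_nasopha and Normal_lung, with 1 point per library and a line at the group mean. Nkx2-1 has a mean of 969 CPM in Normal_lung and 1.23 in Normal_nasopha, and Pax6 0.118 and 60.9.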

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

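Of the tests given here, those of GC content and length for TMPL against TMP and all those on the mesenchymal pattern of the LMP1 libraries were chosen only after the result was seen.

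Genotype effects that differed between libraries with and without the Lung prefix, by the interaction test, were counted for 120 genes and 9 gene lists. None of the 9 lists passed with an estimated correlation (lowest adjusted p 0.0801), and 4 and 5 genes were left without LMP1 replicates 1 and 2. On the log2 scale the effects were 10.62 for Krt23, 10.2 for Abca12, 10.06 for Ppbp, 9.408 for Vnn1, 1.059 for Hmgcs1, 3.384 for Grhl2, 3.423 for Cldn7, 2.427 for Esrp1, 4.648 for Lamb3, 4.485 for Cnfn, 4.582 for Pax9 and 6.153 for Pitx1, and -3.668 for Pcbp4, -2.821 for Gpsm1, -2.705 for Rgma and -2.555 for Amotl2. The sizes for Krt23, Abca12, Ppbp and Vnn1 rest on 3, 2, 19 and 5 counts over the LMP1 libraries and are imprecise. Among 58 sets of 5 libraries checked for 1 library far from the others, 5 were found, where chance gives about 5%. The gap to the nearest library as a share of the range was 0.737 for Mrps21 in TMP (Ctr replicate 1, 13.66 CPM), 0.762 for Psmb9 in TMP (Ctr replicate 3, 3.065 CPM) and 0.964 for Tdrp in TMP (Lung-Ctr replicate 2, 71.42 CPM). It was 0.792 for Psmb8 in TMPL and 0.903 for Rsad2 in TMPL, both from Lung-LMP1 replicate 2 (5.137 and 37.1 CPM).

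Vim and Fn1 were higher and Epcam, Cdh1 and Krt5 lower in both LMP1 libraries than in any other tumour library. Of 21 mesenchymal genes 5 rose against Ctr, 1 fell and 15, Vim among them, were not called, and Ctr replicate 2 had 359 CPM of Vim and more Zeb1 and Col3a1 than either LMP1 library. For the epithelial fall the tables argue against GC content or length, since 23 of 26 epithelial and basal members stayed called after correction, and against the LMP1 genotype by itself, since 0 of the 26 were lower by at least 0.5 times as much in Lung-LMP1 than in Lung-Ctr (median 0.209, against -3.7). Host cells as a large part of the LMP1 libraries are argued against by sex-linked genes. Xist, which female cells carry, was at 0.156 to 0.576 CPM in LMP1, against 1070 to 1140 in the comparator. Ddx3y, which male cells carry, was at 1.14 to 1.47 CPM in LMP1, against 78.7 to 129 in Ctr. A small share of host fibroblasts cannot be told apart from mesenchymal genes of the tumour cells. Of 17 fibroblast list members 1, Col5a1 at 134 and 114 CPM, reached 0.1 times the Vim level in an LMP1 library. Col1a1 was at 1.58 and 0.846 and Col3a1 at 58 and 23.8. One line or clone shared by both LMP1 libraries cannot be told apart from a property of the group, with r = 0.9879 between them across genes, which are not independent replicates, against at most 0.9769 in replicate pairs of the other tumour groups. Both also had little Ddx3y, at 1.142 and 1.472 CPM, while Eif2s3y was at 50.96 and 49.53. A shared line and a shared state could both give this. A state specific to TMPL organoids without the Lung prefix may also account for it and was not tested.

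Genes called between TMPL and TMP followed GC content, with a rho of expression with GC of at least 0.0642 in each TMPL library and at most -0.0895 in each TMP library. The tables argue against depth, since 1708 genes were called with all libraries thinned to 12535166 counts, 1635 of them shared. They also argue against GC content or length of the longest annotated transcript as the whole cause, since 655 of 1647 genes (39.8%) stayed called after correction. A trend with the transcripts actually expressed could remain in these 655 genes and was not tested. For the other 992 genes a GC or length trend of the libraries and an effect of LMP1 cannot be told apart, since both follow genotype, and their median size of change went from 0.684 to 0.445 with SEs of 0.162 and 0.161. Of 100 splits of these libraries within the Lung prefix 1, the real one, gave as many calls (1694, highest other 114). This argues against a chance split of independent libraries, at the smallest share that 100 splits can give. The labels do not show that the libraries are independent, so lines or cultures that differ along with genotype cannot be told apart from it. Nor can primary against metastasis, if the sample descriptions hold. For the Lung prefix the real split called 0 genes, so that all 100 of 100 splits gave as many and the count of splits decides nothing. The highest other, 420, grouped both LMP1 libraries with Ctr replicates 2 and 3 and Lung-LMP1 replicate 1. It may point to a structure of the samples, which was not tested.

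Lung surfactant genes were counted in the nasopharynx libraries, with Sftpc at 0.297%, 0.0699% and 0.0644% of its mean lung level in replicates 1 to 3. Expression by the nasopharyngeal cells is argued against by a common ratio in replicate 1, with Sftpc, Sftpb, Cxcl15, Slc34a2 and Ager at 0.297%, 0.278%, 0.285%, 0.294% and 0.339% of lung, the largest 1.22 times the smallest. Lung material or reads in that library cannot be told apart from other sources, since 0 of 153 genes lay under 0.5 times the prediction but only 16 lay within 2-fold of it, fewer than the 20 set beforehand. For Normal_nasopha against Normal_lung (4935 calls, highest other split 0) and Ctr against the comparator (2917, highest other 0) 1 of 10 splits gave as many calls, and the splits are too few for a share under 0.05.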

How the results depend on the processing

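The length and GC correction and the fit of 13 libraries were chosen after seeing the data, and the other alternatives before. No gene named by rule and called in the main fit changed direction under DESeq2, RLE size factors, no filter, the correction or a left-out library, and named genes were not followed under the other alternatives. The counts of calls by DESeq2 were 3576 for LMP1 against Ctr, 881 for Lung-LMP1 against Lung-Ctr, 40 for Lung-Ctr against Ctr, 2537 for Lung-LMP1 against LMP1, 926 for the interaction, 3115 for TMPL against TMP and 966 for the Lung prefix. The authors' deposited table had 3791 calls for LMP1 against Ctr, 3733 for Lung-LMP1 against LMP1, 4286 for Ctr against the comparator and 6219 for the normal tissues. The length and GC correction gave 937 for LMP1 against Ctr, 796 for TMPL against TMP and 1390 for Ctr against the comparator. Fitting only the 2 groups gave 2682 for Lung-LMP1 against LMP1, leaving out the Lung term 1107 for TMPL against TMP, and the fit of 13 libraries 4944 for Ctr against the comparator. Of 96 list calls 0 passed with an estimated correlation in camera, and fry called 29 lists, 26 of them shared. The cause was not tested for any of these. Leaving out 1 library at a time gave 25 to 1920 calls for LMP1 against Ctr, 0 to 33 for Lung-LMP1 against Lung-Ctr, 0 to 31 for Lung-Ctr against Ctr, 33 to 949 for Lung-LMP1 against LMP1, 4 to 331 for the interaction, 362 to 2116 for TMPL against TMP, 0 to 152 for the Lung prefix, 718 to 3576 for Ctr against the comparator and 2657 to 5421 for the normal tissues. A lone LMP1 or Lung-Ctr library was then assumed to vary like the other groups. With the replicate number as a block the counts were 483 for LMP1 against Ctr, 360 for Lung-LMP1 against LMP1, 2 for the interaction, 826 for TMPL against TMP and 1001 for Ctr against the comparator. The labels do not say whether the numbers pair the samples, and no comparison had every library closest to its own number. In a group of 2 the deviations from the mean mirror each other, so they cannot show that pairing is absent. Ctr 1 had r = -0.0255 with LMP1 1 and 0.0255 with LMP1 2 across genes, which are not independent replicates. The block changed no other count by over 1.5 times. RLE size factors and no filter on low counts moved no count by over 1.5 times. The fit of all 16 libraries was not run because the tables use different gene identifiers. Depth limits genes near the floor. Counting intervals are given for ratios of 2 groups where 1 side has up to 3 counts, but not for interactions.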

Other observations

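The tests on chromosome 16 and on single genes here were chosen after their values were seen. Genes of the Y chromosome were counted in all 4 tumour groups and at 0 in the comparator, but not evenly. Ddx3y (chromosome Y, 1260771 to 1286629), an RNA helicase, had a mean of 102.7 CPM in Ctr, 1.31 in LMP1, 122.3 in Lung-Ctr and 46.2 in Lung-LMP1, where single libraries ran from 7.81 to 76.2. It fell in LMP1 against Ctr (log2 fold change -6.27 ± 0.962 SE, edgeR adjusted p = 0.00711), while Uty had 48.4, 26.3, 56.4 and 30.6 CPM and Eif2s3y 69.0, 50.3, 87.3 and 71.0 in the same order. Kdm5d ran from 2.85 to 45 CPM within Ctr. Xist, the RNA of the inactive X chromosome, was at 1.18 CPM or less in every tumour library and at 1070 to 1140 in the comparator. Hoxa3 was at 14.3, 7.93, 6.57 and 19.04 CPM in the 4 tumour groups.

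Genes on chromosome 16 were higher in Ctr replicate 3 than in the other tumour libraries. Over 423 genes the median deviation from the mean of its libraries was 0.42 on the log2 scale, with 80.4% of genes positive. The other libraries had -0.141 to 0.143 on chromosome 16, and all other values over 20 chromosomes and 10 libraries lay between -0.141 and 0.176.

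Interferon genes spread widely within groups. Isg15 ran from 0.695 to 29.6 CPM in Ctr, from 12.3 to 36.5 in Lung-Ctr, from 0.49 to 17.4 in Lung-LMP1 and from 1.6 to 93.9 in the comparator, but only from 0.128 to 0.415 in LMP1. The basal keratin Krt5 was at 19.9 and 2001 CPM in the 2 Lung-Ctr libraries. Ptprc, a marker of blood cells, was at 0.208 CPM or less in every tumour library. Atp5k, higher in TMPL than in TMP, was at 28.2 CPM in the comparator, near the 40.2 and 30.3 of LMP1 and Lung-LMP1 and above the 4.73 and 1.61 of Ctr and Lung-Ctr. Its longest annotated transcript is 563 bases long. Those of Mrps21, Tmsb10, Polr2j, Ppp1r14b and Hypk, also among the largest rises in TMPL, are 488, 690, 900, 999 and 4170 bases. The median of the genes tested was 3382 bases. Polr2j, Mrps21 and Hypk, at 46.35, 51.0 and 55.3 CPM in the comparator, lay above their means in both TMPL groups. Ppp1r14b, at 162, lay between 187 in LMP1 and 112 in Lung-LMP1, and Tmsb10, at 38.8, lay below both.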
